A study of Drosophila melanogaster with 4 samples.

How the data were processed

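The samples were 2 ChIP libraries for RPD3 and 2 input libraries from Oregon-R wild-type embryos of 14 to 16 h, per the labels. Groups and replicate numbers were taken from the sample titles. Each ChIP replicate had a list of enriched regions of its own, the series had 1 further list, and each input was named in the labels as the control of 1 replicate list. The inputs had no values of their own in what was analysed here. Embryos were crosslinked with formaldehyde before immunoprecipitation, per the labels' protocols.

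Reads were aligned with Bowtie 0.12.7, which is the only tool named, per the submitters' processing notes. Coordinates are on FlyBase release 5, per the file headers. The program that called the regions, its thresholds, any filter on repeats or duplicates, and the way the series-wide list was made are not given in the sources used here. The deposited score of each region was taken as a log2 ratio. That scale was inferred from the deposited values: every score in the 3 lists equalled the log2 of 1 constant per list times a ratio of whole numbers, which holds for base 2. That the ratio is ChIP over input was also inferred, from the labels that pair inputs with lists. Scores are the authors' and were used only to describe, rank or filter regions within a list and to relate partner regions of the replicates. Since calls depend on an unknown threshold and on unknown depth, the number of regions and the covered length of a list can change with sequencing depth alone. No columns of values belonging to other samples were met (0 columns).

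Chromosome lengths were read from the file headers. The 5 large arms sum to 119 Mb. Sequences named as heterochromatin or unplaced were kept in the counts and overlaps and left out of the comparison of arms, and the Uextra sequence held 0 regions in each list. Replicate lists were compared by overlap of at least 1 bp, against 1000 circular shifts of one list along each chromosome, with a one-sided permutation p. The reproducible set was made of combined-list regions overlapped by at least 1 bp of a region of each replicate. Densities per Mb were compared by a chi-square test of region midpoints, for the X, chromosome 4 and each arm against the other autosomal arms, and, as an added test, by 100000 permutations of full 1-Mb bins. Differences in median score between X and autosomes were added after the data were examined and carry 95% intervals from 2000 bootstrap samples of 1-Mb blocks. P-values over regions describe these libraries and do not measure variation between embryo collections.

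The regions named in the text followed a rule fixed before the data were examined: the 15 regions of the reproducible set on 2L, 2R, 3L, 3R, 4 and X with the highest mean percent rank of the replicate scores, and the 5 widest. A bin or region named outside this rule was chosen after its value was seen. Where several regions of a replicate overlapped one region of the set, the highest of their scores was used, which can favour wide regions. The rule also asked for genes, and the plan held tests of promoter overlap, of gene features, of promoter occupancy for 20 gene lists, of 12 sequence motifs and of density per promoter. None of these was run, because the gene table used here is of release 6, no conversion of positions between releases was made, and no annotation or genome sequence of release 5 was used here.

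The overlap test, density ratio, score difference and score-ratio search were tested on simulated lists of 7000 regions. With a true shared share of 57.0%, the observed overlap corrected for chance returned 53.8%. Independent simulated lists overlapped by 22.2% against 22.4% by chance (permutation p = 0.65). A true X density ratio of 0.8 was returned as 0.819, a true X score difference of 0.15 as 0.14, and the simulated score constant of 0.37 was recovered. Alternatives covered the overlap that counts as shared, merging of neighbouring regions within 200 bp, the better-scoring part of each list, the set of regions, omission of each replicate or arm, the placement used for chance, and the unit of the density test. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.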

Results

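RPD3, the Drosophila orthologue of the mammalian histone deacetylases HDAC1 and HDAC2, was mapped by chromatin immunoprecipitation and sequencing in wild-type Oregon-R embryos aged 14 to 16 h. RPD3 is the catalytic subunit of several co-repressor complexes, among them those built on Sin3A, Mi-2 and CoREST, and at this age the embryonic organs are differentiating. The series had 2 ChIP libraries, made with the antibody named Q3451 in the labels, and 2 input libraries, with 1 input paired to each ChIP library. The data were lists of enriched regions: 1 for ChIP replicate 1, 1 for ChIP replicate 2, and 1 for the whole series, called the combined list here. Each region had a start, an end and a score on a log2 scale, read here as enrichment of ChIP over input. The lists held no read numbers, so the depth of each library was unknown and no value below has an error from read counting. With 2 replicates the spread between them is given as an SD over n = 2. The labels did not say whether the replicates came from separate embryo collections, so this spread may be technical only. Coordinates are those of FlyBase release 5, counted from 1, and no gene annotation of that release was used here.

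The first question was how much of the genome RPD3 occupied at this stage. Replicate 1 had 7041 enriched regions and replicate 2 had 7654, a mean of 7347.5 ± 433 (SD, n = 2). On the 5 large chromosome arms, 2L, 2R, 3L, 3R and X, the regions covered 15.4 Mb in replicate 1 and 17.9 Mb in replicate 2, or 14.0% ± 1.49 (SD, n = 2) of the sequence of these arms. The median region was 1866 bp wide in replicate 1 and 1925.5 bp wide in replicate 2, and no region was narrower than 1301 bp in either list. The widest was 14038 bp in replicate 1 and 16631 bp in replicate 2. The median score was 0.81 in replicate 1 and 0.79 in replicate 2, and single scores ran from 0.19 to 4.59 in replicate 1 and from 0.15 to 3.98 in replicate 2. The combined list was longer, with 19364 enriched regions that covered 39.7 Mb, or 33.4%, of the 5 arms. Its median score was 0.54 and its median width 1597 bp. It also held 2 regions marked as depleted, on 2L from 5270340 to 5272057 with a score of -0.11 and on 2R from 11031919 to 11033626 with a score of -0.10. The first of these overlapped a region that replicate 1 listed as enriched, with a score of 0.24, and the second overlapped an enriched region of replicate 2 with a score of 0.25.

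The second comparison asked whether RPD3 was found at the same places in both replicates. Of the regions of replicate 1, 72.7% (5122 of 7041) overlapped a region of replicate 2 by at least 1 bp, and 64.6% (4946 of 7654) of the regions of replicate 2 overlapped one of replicate 1. Sliding one list along each chromosome gave 26.0% and 23.7% on average, so the observed shares were 2.80 and 2.73 times those of chance. The one-sided permutation p was 0.001 in each direction, the smallest that 1000 shifts can give. On the X the shares were 78.3% and 65.8%, and on the autosomal arms 73.2% and 65.3%. In the top quartile of scores on the 5 arms, 88.0% of replicate 1 and 87.9% of replicate 2 regions were shared. Chance gave 30.1% and 28.1% there, from 200 shifts for each quartile. From the lowest to the third quartile the shares were 67.7%, 65.1% and 75.4% in replicate 1 and 49.6%, 55.9% and 68.3% in replicate 2. Chance was 24.2% and 21.8% in the lowest quartile, and higher-scoring regions were wider, with medians of 1563 bp in the lowest and 2838.5 bp in the top quartile of replicate 1, which raises overlap by itself. Shared regions were also wider, with medians of 2108 bp against 1486.5 bp for unshared regions in replicate 1 and 2341 bp against 1517 bp in replicate 2. Over the 5122 regions of replicate 1 that had a partner, the scores of the partners had a Spearman correlation of 0.71 and a Pearson correlation of 0.76. This is a relation across regions of one pair of libraries, and regions are not independent replicates.

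Nearly every replicate region was also in the combined list: 99.5% of replicate 1 and 99.5% of replicate 2. The reverse did not hold. Of the 19364 combined-list regions, 4481 (23.1%) were overlapped by a region of each replicate, 1726 by replicate 1 only, 2467 by replicate 2 only, and 10690 (55.2%) by neither. The 4481 regions found in both replicates are called the reproducible set below. They had a median width of 3477 bp and a median score of 0.69 in the combined list, whereas the regions found in neither had a median width of 1270 bp and a median score of 0.51. On the 5 arms, support from both replicates rose from 7.33% of regions with scores up to 0.4 to 86.8% of regions with scores between 0.8 and 1. Above 1 it was 72.7%, and 22.4% of those 572 regions were in neither replicate list. Wider regions are overlapped more readily, and chance was not subtracted from these shares. The replicate regions that overlap a combined-list region need not overlap each other. How the combined list was made is not given in the sources used here, so its overlap with the replicate lists is not an independent check of either.

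**Figure D1:**
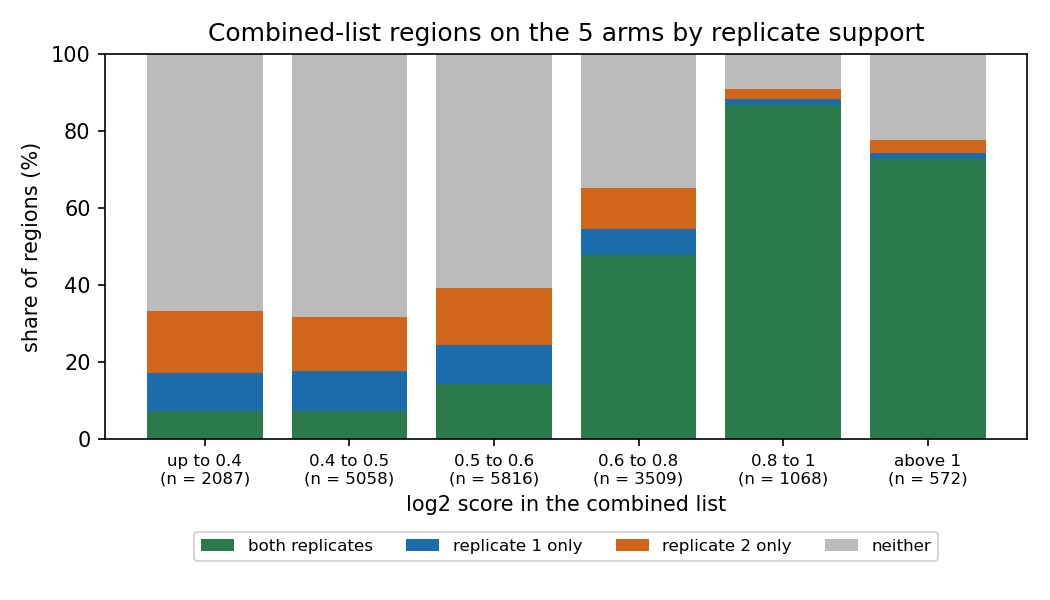
Share of combined-list regions on the 5 large arms (y axis, percent) that were overlapped by a region of both replicates, of one replicate or of neither, by log2 score in the combined list (x axis, with the number of regions per bin). The share found in both replicates was 7.33% in the lowest bin and 86.8% between 0.8 and 1. Shares are not corrected for chance or for region width.

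The third comparison was of chromosomes. The X is dosage compensated in males and chromosome 4 is partly heterochromatic. Arm 2R had the highest density of regions in each replicate, with 72.7 per Mb in replicate 1 and 75.9 per Mb in replicate 2, and 2L had the lowest of the 5 large arms, with 46.8 and 50.8 per Mb. In the reproducible set, 2R had 1.31 times the density of the other autosomal arms (chi-square p = 3.2e-13) and 2L had 0.76 times (p = 1.9e-10). Chromosome 4 had few called regions for its length. It had 14 regions in replicate 1, 18 in replicate 2 and 10 in the reproducible set, for a density 0.20 times that of the autosomal arms (chi-square p = 1.3e-08). Over the combined list, with 64 regions, the ratio was 0.304. Arm 3L had 0.88 times (chi-square p = 0.002) and 3R 1.09 times (p = 0.021) the density of the other autosomal arms. For the X the density ratio was 0.93 in the reproducible set and missed the threshold (chi-square p = 0.08). The ratio for the X was 0.93 in replicate 1 (chi-square p = 0.016) and 0.98 in replicate 2 (p = 0.4), so the call differed between the replicates. In the better-scoring part of the set the ratio was 1.57, which follows by construction from the higher scores of X regions and does not bear on their overall density.

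These chi-square p-values treat regions as independent, which they are not. In a permutation of whole 1-Mb bins between arms, a two-sided test added after the lists had been examined, 2L and 2R kept their calls, with p = 0.0037 for 2L and p = 0.0017 for 2R (0.0092 and 0.0085 after Benjamini-Hochberg adjustment over the 5 arms). In the reproducible set the other arms did not pass, with permutation p = 0.25 for 3L, 0.38 for 3R and 0.52 for the X, nor did they in either replicate list. In the combined list the same permutation test passed for 3R (ratio 1.12, adjusted p = 0.038) and for the X (ratio 0.885, adjusted p = 0.04) as well as for 2L and 2R, so the calls for 3R and the X differed by list. Chromosome 4 has 1 full bin, with 5 regions of the reproducible set, fewer than in any of the 95 autosomal bins (two-sided exact permutation p = 0.021, the smallest that these bins allow). Along the arms the replicates had much the same profile. Over 117 bins of 1 Mb, the region counts of the replicates had a Spearman correlation of 0.94 and a Pearson correlation of 0.96, across bins of one pair of libraries. In each replicate list the bin with the fewest regions was 2L from 17 to 18 Mb, with 10 regions in replicate 1 and 12 in replicate 2. In the reproducible set that bin had 8 regions, and the lowest was 3L from 23 to 24 Mb, with 6. The bin with the most was 2R from 20 to 21 Mb, with 129 in each replicate and 82 in the reproducible set.

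**Figure D2:**
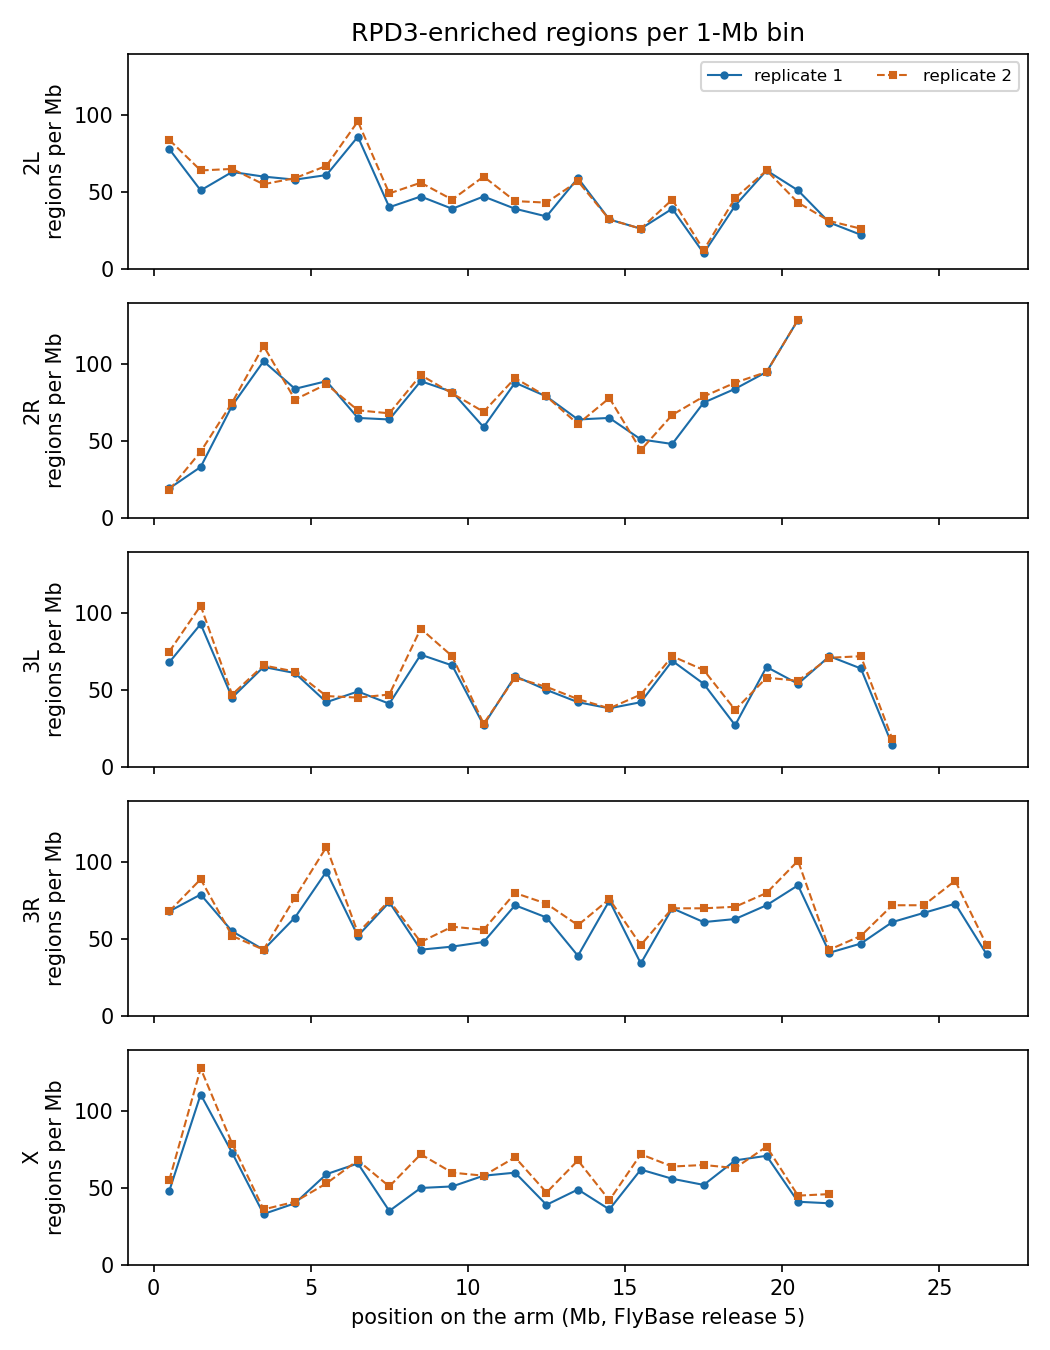
Enriched regions per full 1-Mb bin (y axis) along the 5 large arms (x axis, position in Mb on FlyBase release 5) in replicate 1 (circles) and replicate 2 (squares). Both lines dip to 10 and 12 regions on 2L at 17 to 18 Mb and reach 129 on 2R at 20 to 21 Mb.

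Regions on the X had higher scores than regions on the autosomes, a comparison made after the lists had been examined. In replicate 1 the median score was 0.96 on the X, over 1200 regions, and 0.78 on the autosomal arms, over 5582 regions. The difference was 0.18, with a 95% interval of 0.16 to 0.20 from a bootstrap of 1-Mb blocks. In replicate 2 the medians were 0.93 and 0.77, a difference of 0.16 (95% interval 0.15 to 0.18). The mean difference of 0.17 ± 0.01 (SD, n = 2) corresponds to a ratio of 1.13 on a linear scale. The 4 autosomal arms were close to one another, with medians from 0.77 to 0.78 in replicate 1 and from 0.76 to 0.77 in replicate 2. Of the X regions, 33.6% in replicate 1 and 28.1% in replicate 2 lay above the autosomal 90th percentile. The difference was 0.10 in the combined list and 0.05 within the better-scoring part of the reproducible set, where the selection itself was on scores.

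**Figure D3:**
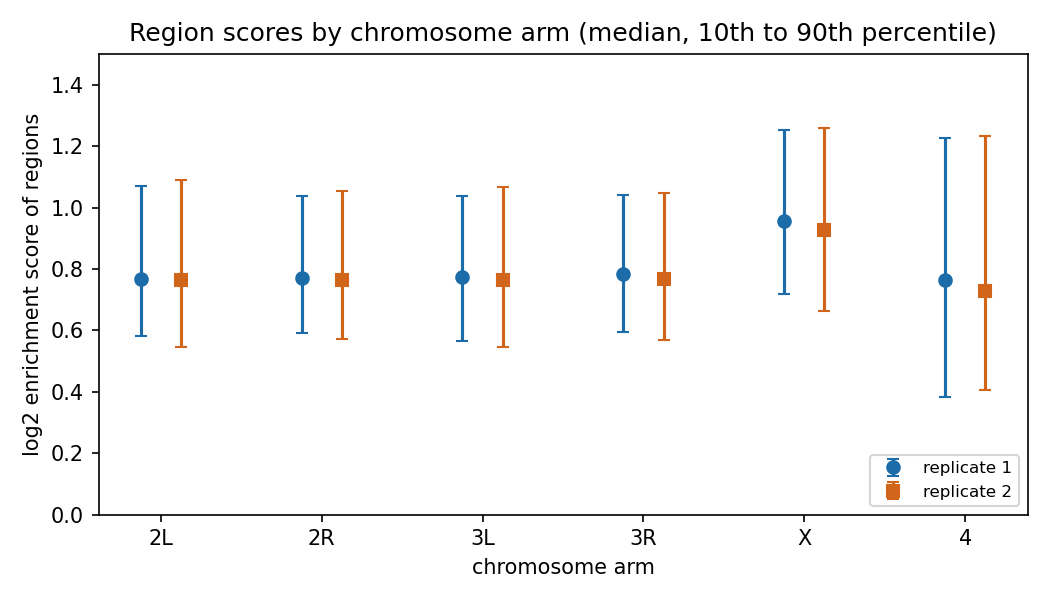
Log2 scores of enriched regions (y axis) by chromosome arm (x axis) in replicate 1 (circles) and replicate 2 (squares). Points are medians over regions and bars run from the 10th to the 90th percentile. The X medians are 0.96 and 0.93, above those of the 4 autosomal arms.

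The strongest sites were named by the rank of their scores in both replicates, and 10 of the 15 top-ranked regions of the reproducible set were on the X, where 780 of the 4391 ranked regions lay (two-sided Fisher's exact p = 3.8e-05, a test added after the ranking was seen and not independent of the higher X scores). The first was on 2R from 2160482 to 2162520, with a score of 2.67 in replicate 1 and 1.86 in replicate 2. Next came X from 8292047 to 8296951, where the best of 2 regions in each replicate scored 2.51 and 1.82. X from 19413186 to 19418693 followed, with scores of 1.85 and 1.90. The fourth was on 2L from 22661862 to 22664244, near the centromere end of the arm, with scores of 2.21 and 1.69. A region of 16964 bp on 2L, from 11996505 to 12013468, had best scores of 1.61 among 2 regions of replicate 1 and 1.87 among 3 of replicate 2. The other X regions lay from 1368685 to 1375296, 1891376 to 1896143, 6180616 to 6192971, 6709884 to 6721819, 9498720 to 9506583, 19368742 to 19378186, 19575157 to 19580340 and 20261619 to 20268443. On 3R the list held 16150981 to 16155570 and 23551409 to 23552897. Neither 3L nor chromosome 4 had a region among the 15.

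The 5 widest regions of the reproducible set each held several replicate regions. The widest, on 3R from 8231915 to 8261414, spanned 29.5 kb and contained 6 regions of replicate 1 and 5 of replicate 2. It was followed by 2R from 19430569 to 19454958 (24.4 kb, 5 and 7 regions) and by X from 11001503 to 11023764 (22.3 kb, 4 regions in each replicate). The last of the 5 were 3R from 12064630 to 12085687 (21.1 kb, 6 and 4 regions) and 2L from 1155285 to 1174367 (19.1 kb, 3 and 4 regions). The genes at these positions were not analysed here.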

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

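The tests of X scores against a calling threshold and against a single offset, and the test of recurrence on unplaced sequences, were chosen after their results were seen; the tests of region width and of small numbers were written before theirs.

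Regions on heterochromatic and unplaced sequences drew attention because no comparison of arms used them and yet they carried signal: 245 in replicate 1, 223 in replicate 2 and 1190 in the combined list. Their median score exceeded that of the autosomal arms by 0.37 in replicate 1 (95% interval 0.28 to 0.43) and by 0.30 in replicate 2 (0.25 to 0.44). The intervals in this paragraph came from a bootstrap of single regions. That treats regions as independent, which they are not, so the intervals may be too narrow. Of these regions, 35.9% in replicate 1 and 39.0% in replicate 2 were found in the other replicate (chance 4.36% and 4.73%). They recurred less often than regions of the autosomal arms, with 73.2% and 65.3% (chance 26.8% and 24.6%). Calls that do not recur are still argued against as the whole cause. The regions here that did recur scored above shared autosomal regions, by 0.34 (0.24 to 0.44) and 0.255 (0.16 to 0.39). Within the replicate lists, unshared regions here differed from shared ones by 0.01 (-0.15 to 0.15) and by less than 0.01 (-0.15 to 0.22), while in the combined list those in neither replicate had a median of 0.93 against 0.85 for those in both, the reverse of the 5 arms (0.50 against 0.69). Small read numbers as the whole cause stay open. Some regions had a score ratio whose denominator, in lowest terms, was at least 30 (65 and 69 regions). Among these the difference was 0.14 (0.03 to 0.18) and 0.039 (-0.02 to 0.09), above 0 in one replicate only and below the 0.37 and 0.30 over all regions. Denominators were also smaller here, with medians of 14 and 16 against 52 and 61 on the autosomal arms. They equalled 1 in 16.7% and 11.7% of regions here, against 1.58% and 1.06% there. Reduced denominators are not read numbers and depend on the constant chosen for each list, so this test cannot decide. No biological explanation was tested.

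The X scores are the other pattern in these lists. A stricter calling threshold on the X as the whole cause is argued against, since it would remove weak regions and add no strong ones, yet regions above the autosomal 90th percentile were 3.11 times as dense on the X in replicate 1 and 2.75 times in replicate 2. Counting noise from smaller read numbers stays open. Among the widest regions (upper quartile of width), the difference was 0.144 in replicate 1 (95% interval 0.11 to 0.17) and 0.15 in replicate 2 (0.13 to 0.18). Both were above the bound set beforehand. However, these regions were at least 2549 bp and 2774 bp wide, against medians of 1866 bp and 1925.5 bp over each list. Noise need not fall below that bound over so small a change in width, so the test cannot decide. One offset of the ChIP to input ratio along the whole X also stays open, and no source of such an offset was tested. The difference varied by 0.07 in replicate 1 and by 0.0931 in replicate 2 over the 10th, 50th and 90th percentiles. Both values lay within the range written for a single offset. That range was set after the results were seen, so the test cannot decide. Signal outside the called regions, which would decide, was not analysed here. No biological explanation was tested, since the design has no group of another sex, stage or genotype.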

How the results depend on the processing

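The bin permutations, the omission of single arms, the restriction of replicate overlap to the 5 large arms and all alternatives for the X score difference and for unplaced sequences were chosen after the results were seen. Across all results, 68 alternative values kept their direction and side of the threshold or stayed within the set range. By construction, keeping the better-scoring part of each list (scores at or above the median) lowered the counts to 3563 regions in replicate 1, 3830 in replicate 2, 9684 in the combined list and 2120 in the reproducible set. The X density ratio of 0.93 (chi-square p = 0.08) was the least stable result. It was 0.88 over the combined list (chi-square p = 1.4e-10) and 0.93 to 0.98 on a single replicate. It was 0.88 without 2L (chi-square p = 0.0017) and 0.91 without 3L (p = 0.015). Without 3R it was 0.96 (chi-square p = 0.28) and without 2R 0.997 (p = 0.95), so it depended on the arms compared. In the better-scoring part it was 1.57 (chi-square p = 5.7e-21), where the direction turned by construction, since X scores are higher. A permutation of 1-Mb bins ended the calls for 3L (0.90, p = 0.25) and 3R (1.08, p = 0.38) in the reproducible set, though over the combined list it passed for 3R (1.12, adjusted p = 0.038) and for the X (0.885, adjusted p = 0.04), and keeping the better-scoring part ended that for 3R (1.11, chi-square p = 0.055). Chromosome 4 kept its call in every alternative run, with ratios from 0.13 in its 1 full bin to 0.30 over the combined list. The Spearman correlation of partner scores fell from 0.71 to 0.60 given region width. The X score difference stayed above 0 in every alternative run, from 0.05 in the better-scoring part to 0.18 without replicate 2. Replicate overlap ran from 61.0% to 74.1% of replicate 1 and from 56.1% to 65.4% of replicate 2, against chance drawn 200 times per setting. No paired analysis was possible because the inputs had no values of their own. The alternatives listed for promoters, gene features, gene lists and motifs were not run, for want of an annotation of release 5. Depth was unknown, so its effect on the length of each list could not be measured.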

Other observations

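The tests of spacing and of how scores are built, and the counts of the bins next to the centromeres, were chosen after the results were seen. The tests of regions missing from both replicate lists were written before.

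The called regions were clumped along the arms, compared with random placement. In replicate 1, 27.7% of the gaps between neighbouring regions were at most 2 kb, against 12.6% when the same widths were placed at random without overlap, and in replicate 2 the shares were 29.3% and 14.0%. The median gap was 5421 bp in replicate 1, against 10393 bp for random placement, and 4997 bp against 9289 bp in replicate 2. In the reproducible set 26.9% of gaps were at most 2 kb, against 8.53% (permutation p = 0.001 in each of these lists, the smallest that 1000 placements can give). The placement took no account of differences in density along an arm, nor of a wide domain called as several regions. Merging regions within 200 bp left 6742 of 7041 in replicate 1 and 7297 of 7654 in replicate 2. How much of the excess comes from either was not tested.

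In both replicate lists, regions next to the centromere were fewer than in any other bin of the arm on 2R and 3L, and not on 2L, 3R or the X. In the last full Mb on the centromere side of 3L, from 23 to 24 Mb, there were 14 regions in replicate 1 and 18 in replicate 2, against medians of 54 and 58 and minima of 27 and 28 over the other bins of the arm. The first Mb of 2R had 19 and 18 regions, against medians of 77 and 78.5 and minima of 33 and 43. On 2L from 22 to 23 Mb there were 22 and 26, against medians of 47 and 52, but other bins of 2L went down to 10 and 12. On the X from 21 to 22 Mb there were 40 and 46, against medians of 52 and 63, and other bins went down to 33 and 36, although in the combined list this X bin, with 100 regions, was the lowest of its arm (minimum of the others 112). The first Mb of 3R had 68 in each replicate, against medians of 62 and 70.5. These are counts of single bins, without a test.

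The 9821 combined-list regions of the 5 arms that were in neither replicate list are a further pattern. Calls scattered evenly along each arm as the whole cause are argued against: 32.9% lay within 5 kb of a region found in both replicates. That was 1.39 times the 23.7% obtained by random placement outside the other regions, and above the highest of 200 placements (24.9%). The placement took no account of differences in density along an arm, so part or all of this excess may come from region-rich stretches. Chance calls that follow local density therefore stay open. Fragments split off the edges of stronger regions are argued against as the main source, because 14.3% lay within 500 bp of a region that a replicate list also held. Weak binding that passes a threshold once reads are pooled was not tested and stays open. The smallest width did differ between the lists: the combined list held regions narrower than 1301 bp, the narrowest in each replicate list. The regions in neither replicate list had a median width of 1270 bp, so most were narrower than any replicate region. These widths go with a smallest allowed width that was lower for the combined list. The limits used in calling are not given, and how much of the pattern such a difference accounts for was not tested and stays open.

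The scores take repeated values, and a candidate explanation is that each is the log2 of a constant of its list times a ratio of whole read numbers. With denominators up to 2000 and a relative tolerance of 1e-10, 100% of scores in each list matched such a value, against 0.114%, 0.105% and 0.0775% of scores moved by a small random amount. The constants taken were 0.438 in replicate 1, 0.479 in replicate 2 and 0.458 in the combined list. The match alone does not fix them, since a constant that differs by a simple factor can match too. They were picked as the candidates at which small primes divided numerators and denominators about equally often. The next best were 0.219, 0.239 and 0.917, and the denominators below depend on this choice. The denominators, in lowest terms, may be reduced numbers of input reads: the upper quartile of denominators per kb of region was lower on the X than on the autosomal arms, by a factor of 0.694 in replicate 1 and 0.709 in replicate 2, in the direction of the lower X dose of a population of both sexes. The numerators were lower on the X too, by 0.773 and 0.777, so this test does not tell input reads from other read numbers, and what the denominators count stays open. On the autosomal arms the upper quartile was 40.1 per kb in replicate 1, 46.4 in replicate 2 and 84.5 in the combined list, where the replicates sum to 86.5. These reduced ratios are not depths and no interval was computed from them.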
